A study of Mus musculus with 17 samples.

How the data were processed

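RNA from whole nasal turbinates of mice, the scroll-shaped bones of the nose with their mucosa and glands, had been sequenced per the labels' protocols with a bulk form of MARS-seq, which tags each transcript with a unique molecular identifier (UMI) so that amplified copies of a molecule are counted once. The submitters' processing notes name cutadapt, STAR, HTSeq and the mm10 genome; their versions and the gene annotation were not given in the sources used here. The deposited table holds the authors' raw UMI counts per gene, which were used as deposited. It also holds the authors' signal values, which are those counts divided by a constant per library (checked on every value: the ratio varied by at most 1.6e-14 within a library), and the authors' values on a log2 scale; neither entered a test. The authors' deposited comparison gives a log2 fold change, a p-value, an adjusted p-value and a pass mark per gene. The meaning of its column name was inferred from the values: its log2 fold changes correlated at 0.996, across genes, with a contrast of the boosted group against the mean of the other groups. The column names of all 17 libraries matched their labels.

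The table lists 15115 genes, each with at least 6 UMIs in 1 or more libraries. No immunoglobulin chain gene was analysed here, so 3 results planned before the data were examined (the IgA heavy chain share, the immunoglobulin share and the level of Igha) were not computed, and the alternative that leaves immunoglobulin genes out had nothing to remove. Mitochondrially encoded genes were likewise not analysed here.

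Libraries were grouped by the labels as naive (n = 5), prime (n = 5) and PandB, for prime and boost (n = 7). The design text calls them biological replicates. Naive and prime are numbered 1 to 5, and PandB 1, 2, 3, 4, 6, 9 and 10. Whether boosted samples were left out cannot be told from the labels. The labels do not name the animals, any batch or the hour of collection, so p-values measure the spread between these samples. A batch or hour that went with a group could not be separated from its treatment. No 2 libraries of a group agreed within sampling noise: the chi-square of their counts per degree of freedom was at least 4.07. Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM normalization, filterByExpr by group, which left 12407 genes, robust quasi-likelihood fits of all 17 libraries with the group alone, and Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) of log2 fold changes were the absolute change over the square root of the F statistic. CPM values are UMI counts over the TMM-scaled library total, as edgeR's cpm function gives them. A contrast of PandB against the mean of naive and prime was added after the data were seen, to set beside the authors' deposited table.

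A total of 50 gene lists for cell types, pathways and RNA quality were fixed before the data were examined; 5 had no listed member and 41 had at least 3 tested members. They were tested two-sided with camera in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the 41 lists, and again with the correlation estimated from the data; fry was an alternative. A few short lists for the closing tests were written after the data were seen. The genes named in the text followed a rule fixed before the data were examined: per comparison, up to 8 called genes of lowest p in each direction, then members of lowest p in each list that passed or held 3 or more called genes, then a set of IgA, homing and T cell genes whatever their p. Genes named in the added contrast and in the closing section were chosen after their values were seen. Gene positions are from GENCODE vM21 on GRCm38, the same assembly as mm10; 14868 of the 15115 symbols matched it by name.

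The alternatives fixed beforehand were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, library totals alone, no filter, a stricter filter (at least 10 UMIs in at least 5 libraries and a mean CPM of at least 10), a fit of only the groups compared, the replicate number as a block, the library total or the olfactory neuron score as a covariate, and each library left out in turn. An alternative without libraries of very low depth was not run, because no library fell under the limit planned for it. Added after the data were seen were fits without PandB replicates 6 and 10, without the 2 shallowest libraries, and with the ribosomal protein or ciliated cell score as a covariate.

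The fits were tested on simulated counts drawn from the real means, totals and dispersions, with 200 genes changed. For PandB against naive, with 12300 genes tested, 64.1% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 95.2% of those changed 4-fold were called in the right direction, and 9 of 234 calls were of unchanged genes; the calls include genes of the lists shifted below. For prime against naive (12294 genes) the shares were 50% (1.5-fold), 70.1% (2-fold) and 97% (4-fold), and for PandB against prime (12294 genes) 38.8%, 81% and 98.5%. All 10 random lists shifted by 0.5 on the log2 scale were called in each comparison, and none of the 31 others. These genes were simulated as independent, unlike real ones. Library totals ran from 1396736 to 4498950 UMIs, so 1 CPM before scaling stands for 1.4 to 4.5 UMIs.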

Results

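The turbinates of naive, primed, and primed and boosted mice were profiled to describe their transcriptome 7 days after the boost, in a series concerned with the origin of cells that secrete IgA in the nasal glands. The naive libraries (n = 5) held 1396736 to 4498950 UMIs each. The prime libraries (n = 5) held 1430972 to 4415679, and the PandB libraries (prime and boost, n = 7) 2138649 to 4299133. The 10 most abundant genes took 18.9% ± 6 (SD, n = 5) of the UMIs in naive, 17.9% ± 3.1 (SD, n = 5) in prime and 12.6% ± 1.6 (SD, n = 7) in PandB. All gene tests below are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over 12407 genes. List tests are two-sided camera tests adjusted over 41 lists.

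After prime and boost, the 6 tested genes of the fixed list of 21 inflammatory cytokines and chemokines were higher as a set than in naive turbinates (median log2 fold change 1.66, 2 of 6 called, camera adjusted p = 0.00204 with an estimated correlation). So were the single genes Lcn2, Pigr and Ccl28. Cxcl5, a neutrophil-attracting chemokine (chromosome 5, 90759360 to 90761624, GRCm38), rose from 27.3 ± 5.64 CPM (SD, n = 5) to 95.1 ± 22.3 CPM (SD, n = 7), a log2 fold change of 1.76 (SE 0.166, edgeR adjusted p = 1.03e-05). Lcn2, an iron-sequestering antimicrobial protein (chromosome 2, 32384633 to 32388252), rose from 125 ± 34.6 to 1090 ± 638 CPM (log2 fold change 3.11, SE 0.403, adjusted p = 0.00276). Pigr, the receptor that carries polymeric IgA across epithelium (chromosome 1, 130826684 to 130852249), rose from 189 ± 46.2 to 397 ± 81.9 CPM (log2 fold change 1.08, SE 0.172, adjusted p = 0.00539). Ccl28, a chemokine that draws IgA plasmablasts to mucosal surfaces (chromosome 13, 119623819 to 119654359), rose from 24.2 ± 4.35 to 66.5 ± 19.9 CPM (log2 fold change 1.47, SE 0.222, adjusted p = 0.00333). For each of these 4 genes all 7 PandB libraries lay above all 10 others. In all, 93 genes were called, 74 higher and 19 lower, but without naive replicate 1 the split was 46 higher and 58 lower of 104.

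**Figure D1:**
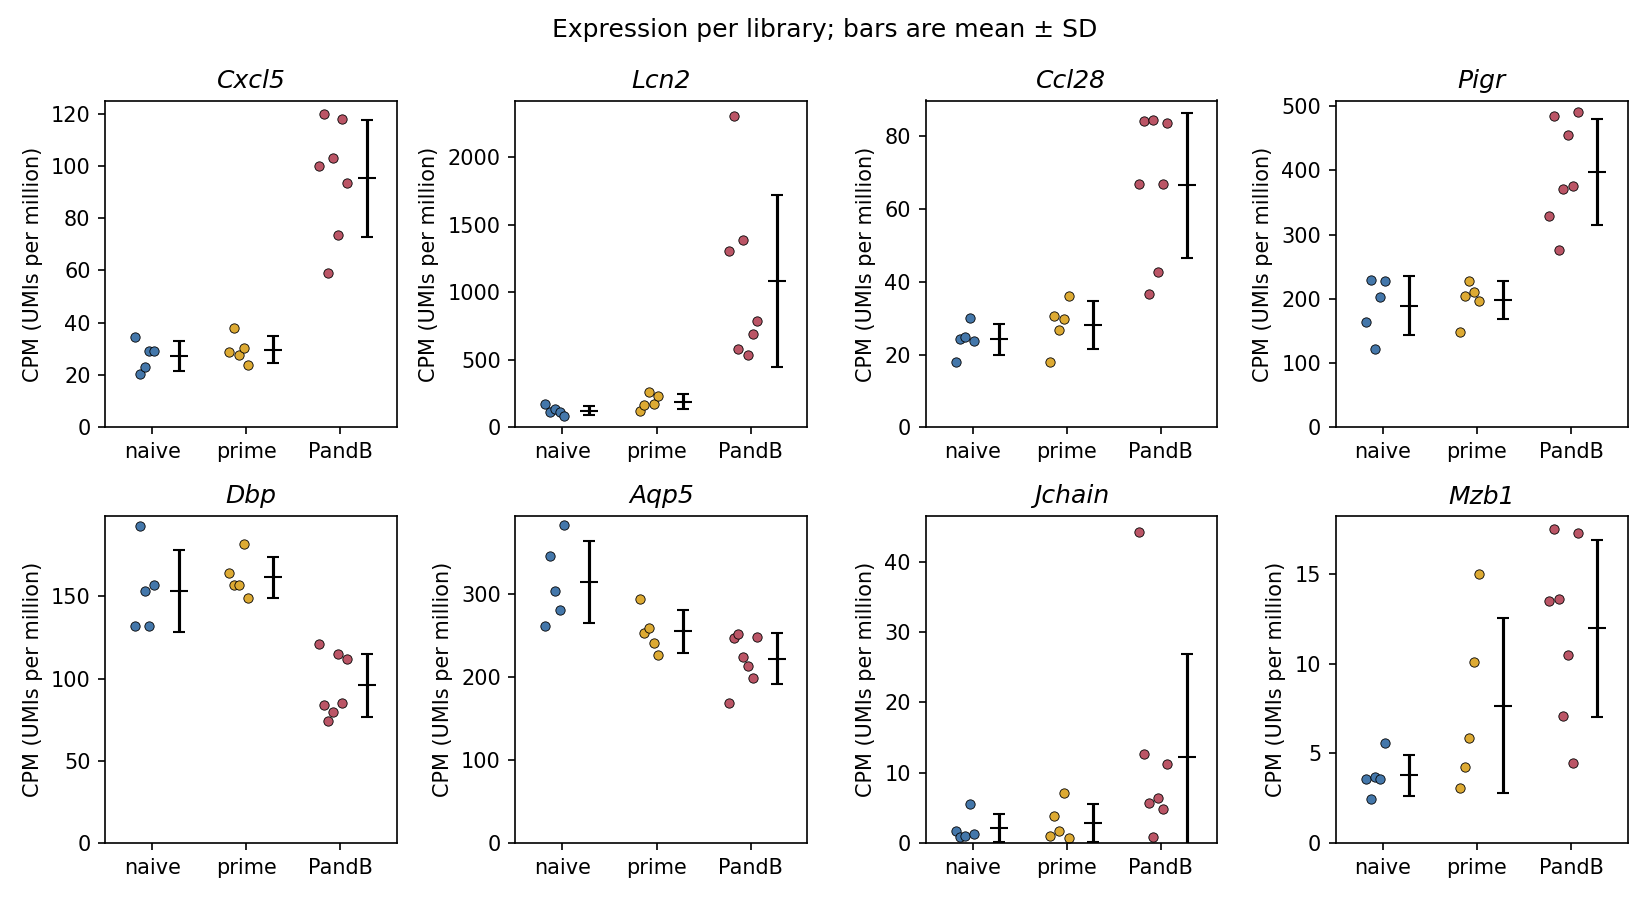
CPM per library (vertical axes, linear and starting at 0) for 8 genes in the naive (n = 5), prime (n = 5) and PandB (n = 7) groups; points are libraries and the bars beside them are the mean ± SD, cut at 0 for Jchain. All 7 PandB libraries lie above all others for Cxcl5, Lcn2, Ccl28 and Pigr, and below them for Dbp, while the highest Jchain value, 44.2 CPM, is that of 1 PandB library.

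Among the genes of lowest p, 6 others were higher, with adjusted p between 0.00204 and 0.00276. They were Il1r2, the decoy receptor for interleukin 1 (log2 fold change 2.20), Il1b (2.51), Pirb, an inhibitory receptor of myeloid and B cells (1.45), the membrane mucin Muc4 (1.08), the complement component C1qc (0.60) and the tubulin gene Tubb2a (0.47). The genes lower at lowest p were Lsm14b (-0.53), the clock-controlled transcription factor Dbp (-0.66), Nat8f1 (-0.63), Bckdha (-0.46), the gland water channel Aqp5 (-0.50), Ss18l2 (-0.42), the ribosomal protein gene Rpl35 (-0.49) and Polr2e (-0.34). Their adjusted p ran from 0.00298 to 0.034. Rpl35 was past the threshold in 18 of 31 alternatives, Polr2e and Ss18l2 in 20, Aqp5 in 25 and the rest in 28 to 30. Without naive replicates 2 and 5, each left out in turn, 5 and 4 genes were called lower in place of 19. Dbp was at 153 ± 24.8 CPM (SD, n = 5) in naive and 95.9 ± 19.4 CPM (SD, n = 7) in PandB. Aqp5 was at 315 ± 49.4 and 222 ± 30.9 CPM.

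With an estimated correlation, 11 of the fixed lists passed, all higher. Inflammatory cytokines and chemokines had the highest median, 1.66 on the log2 scale (camera adjusted p = 1.03e-14, and adjusted p = 0.00204 with an estimated correlation). Of its 6 tested members 2 were called over all genes, Cxcl5 and Il1b, and 4 adjusted over the list alone. The list names 21 genes, of which 14 were listed, so the median describes only the genes that passed the filter. A gene low in naive and prime can pass it through PandB alone and raise the median. Csf3 of this list was at 0 to 2.27 CPM in naive and prime and at 0.378 to 7.31 CPM in PandB. Of the T cell and dendritic cell lists below, 6 of 22 and 7 of 15 named genes were tested. Under the stricter filter these lists and the inflammatory list kept too few members to be tested. MHC class II genes had a median of 0.80, with 2 of 8 called, H2-DMa (0.79) and H2-DMb1 (0.64), and 6 adjusted over the list alone (adjusted p = 0.0195 with an estimated correlation). Complement genes had 5 of 12 called, among them C1qa (0.54), C1qb (0.48) and C3 (1.47), and 6 adjusted over the list alone. Macrophage and monocyte genes had 3 of 14 called, the C1q genes that both lists hold, and 6 adjusted over the list alone. Their adjusted p was 0.0195 and 0.0243 with an estimated correlation. Mucosal homing chemokines had 2 of 9 called, Ccl28 and Ccl20 (1.32), and 3 adjusted over the list alone. Leukocyte adhesion molecules had 3 of 11 called, Selplg (1.23), Itgb2 (0.97) and Icam1 (0.89), and 5 adjusted over the list alone. Their adjusted p was 0.0195 and 0.0227 with an estimated correlation. T cell genes (median 0.87, with Lat at 1.17 called), dendritic cell genes (0.50, with Ccl22 at 1.17 called) and mucous and goblet genes (0.42) had 4, 5 and 1 members adjusted over the list alone, each at adjusted p = 0.0195 with an estimated correlation. Immunoglobulin transport genes (0.14, with Pigr the 1 gene called of 6) and tuft and ionocyte genes (0.38) had 1 and 3, at adjusted p = 0.0262 and 0.045 with an estimated correlation. Muc5b, a mucin of the goblet list, was at 0.70 (edgeR adjusted p = 0.0768) and passed in 7 of 31 alternatives.

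A further 16 lists passed camera only with the preset correlation. Interferon gamma response genes (median 0.43) had Serpina3g (1.59) and Psmb8 (0.72) called, and MHC class I genes (0.45) had Nlrc5 (1.44) and Psmb8, with adjusted p = 0.0595 and 0.0531 with an estimated correlation. Antimicrobial genes (0.67) had Lcn2 and Chil1 (3.04) called, neutrophil genes (0.61) Il1r2 and Csf3r (1.84), and club cell genes (0.56) Muc4, with adjusted p = 0.0529, 0.103 and 0.0597 with an estimated correlation. Adjusted over the list alone, these 5 lists had 3, 5, 2, 2 and 4 higher genes. B cell genes had a median of 0.78, with 0 of 11 called and 3 adjusted over the list alone. Fcmr had the lowest p of them, at 2.0 (edgeR adjusted p = 0.172), and the list was at adjusted p = 0.103 with an estimated correlation.

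Cytosolic ribosomal protein genes had a median of -0.20, with 5 of 90 called lower, Rpl35 and Rpl31 (-0.41) among them. Adjusted over the list alone 25 were lower and 1 higher, and the list was at adjusted p = 0.103 with an estimated correlation. Serous and acinar gland genes had a median of -0.42, with Aqp5 called of 31 tested, and 7 lower and 1 higher adjusted over the list alone. Obp1a, an odorant-binding protein of that list, was at -2.25 (edgeR adjusted p = 0.119), and the list was at adjusted p = 0.178 with an estimated correlation. With the ribosomal score as a covariate the median of the gland list turned to 0.117 against naive (camera adjusted p = 0.257), and from -0.281 to 0.242 against prime (camera adjusted p = 0.00597). Unfolded protein response genes (-0.13), circadian clock genes (-0.17) and olfactory neuron genes (-0.08) also had negative medians, with adjusted p = 0.215, 0.136 and 0.649 with an estimated correlation. Scaling by library totals alone turned the first and the last of these positive (0.02 and 0.06), and the ribosomal score as a covariate turned the first to 0.0367. Immediate early genes (0.23), CD8 T and NK genes (0.86), basal cell genes (0.23), type I interferon genes (0.17) and ciliated cell genes (0.19) had positive medians, with adjusted p of 0.136, 0.0597, 0.18, 0.305 and 0.649 with an estimated correlation.

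Plasma cell genes did not pass the list test. Their median was -0.07 and their mean 0.335 over 15 tested genes (camera adjusted p = 0.669), and 0 were called over all genes, while 4 were higher and 1 lower adjusted over the list alone. Scaling by library totals alone turned the median to 0.095. A rise of plasma cells was thus neither shown nor excluded by this list. In RNA of whole turbinates the cells that expressed each gene were not told apart. Xbp1 was at 315 to 561 CPM in naive, where Mzb1 was at 2.44 to 5.59 CPM. Jchain, which joins polymeric IgA, was at 2.09 ± 2 CPM (SD, n = 5) in naive and 12.2 ± 14.6 CPM (SD, n = 7) in PandB (log2 fold change 2.41, SE 0.844, edgeR adjusted p = 0.277). PandB replicate 1 held 44.2 CPM and the other PandB libraries 0.786 to 12.6 CPM; without that library the log2 fold change was 1.57. Mzb1, an endoplasmic reticulum protein of antibody-secreting cells, was at 3.78 ± 1.14 and 12 ± 4.93 CPM (log2 fold change 1.61, SE 0.384, edgeR adjusted p = 0.0569). Mzb1 was past the threshold in 7 of 30 alternatives, DESeq2 (adjusted p = 0.0036) among them, with adjusted p from 0.0036 to 0.279, and Jchain in 0 of 30. Xbp1 (-0.24, adjusted p = 0.602), Vcam1 (0.05, adjusted p = 0.982), Cd4 (1.32, adjusted p = 0.121) and Arntl (0.59, adjusted p = 0.111) were not called; Cd4 passed in 2 of 30 alternatives, Arntl in 1 of 31, and Xbp1 and Vcam1 in 0. Cxcl9 and Itgae were too low to be tested, at 0.938 and 1.29 CPM in naive and 0.819 and 2.18 CPM in PandB.

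The number of genes called against naive was 59 without naive replicate 2 or 3, 35 without naive replicate 5, and 37, 60, 57 and 49 without PandB replicates 1, 2, 6 and 10; without PandB replicates 6 and 10 together it was 41. Leaving out each library in turn, C3 and Ccl22 lost their call in 13 of 17 fits, Icam1 in 12 and Rpl31 in 10. Scaling by library totals alone moved the median of all genes by 0.145 on the log2 scale and gave 210 higher and 4 lower genes, a share of higher calls of 98.1% in place of 79.6%, so directions are given relative to the median gene.

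The boosted group was next set against the primed group to ask what differed between animals that had and had not been boosted. Here 23 genes were called, 20 higher and 3 lower, and 19 of them were also called against naive, all in the same direction. Cxcl5 rose by a log2 fold change of 1.66 (SE 0.166, edgeR adjusted p = 2.92e-05). Il1r2 (2.01), the tight junction gene Tjp3 (0.56), Clca3a2 (3.25), clusterin Clu (0.64), Slfn2 (1.01), Serpina3g (1.5) and Serpina3n (1.75) came next by p, with adjusted p from 0.0053 to 0.015. Lcn2 (2.52), Pigr (1.01), Ccl28 (1.27), Ccl20 (1.35), the secreted mucin Muc5b (1.01), Il1b (1.81) and the B cell gene Cd72 (1.18) were also called, with adjusted p from 0.0157 to 0.0498. Muc5b was at 239 ± 64.2 CPM (SD, n = 5) in prime and 484 ± 98.2 CPM (SD, n = 7) in PandB. The 3 lower genes were Dbp (-0.76, adjusted p = 0.0053), the bone matrix gene Mepe (-1.03, adjusted p = 0.0221) and Rtl8a (-0.76, adjusted p = 0.0438).

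With an estimated correlation 2 lists passed, both at adjusted p = 0.00426. Inflammatory cytokines and chemokines had a median of 1.34 with 2 of 6 called, and mucous and goblet genes a median of 0.29 with 1 of 12 called; each had 4 adjusted over the list alone. With the preset correlation 26 lists passed, 19 higher and 7 lower. Ribosomal protein genes had a median of -0.22, with 0 of 90 called over all genes and 38 lower adjusted over the list alone (adjusted p = 0.136 with an estimated correlation). MHC class II (0.52) and complement genes (0.33), with 6 members each adjusted over the list alone, were both at adjusted p = 0.096 with an estimated correlation. Circadian clock genes had a median of -0.11 (adjusted p = 0.203 with an estimated correlation), which scaling by library totals alone turned to 0.00369. Nfil3, a repressor of clock output, was at 0.69 (edgeR adjusted p = 0.111). Jchain (1.90, adjusted p = 0.496), Mzb1 (0.73, adjusted p = 0.578), Xbp1 (-0.24), Vcam1 (-0.20) and Cd4 (0.95) were not called. The count was 7, 11 and 10 without prime replicates 1, 2 and 5, 15 without PandB replicate 2 and 35 without naive replicate 1. Cd72 and Rtl8a each lost their call in 12 of 17 such fits. Il1b was past the threshold in 18 of 30 alternatives here.

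**Figure D2:**
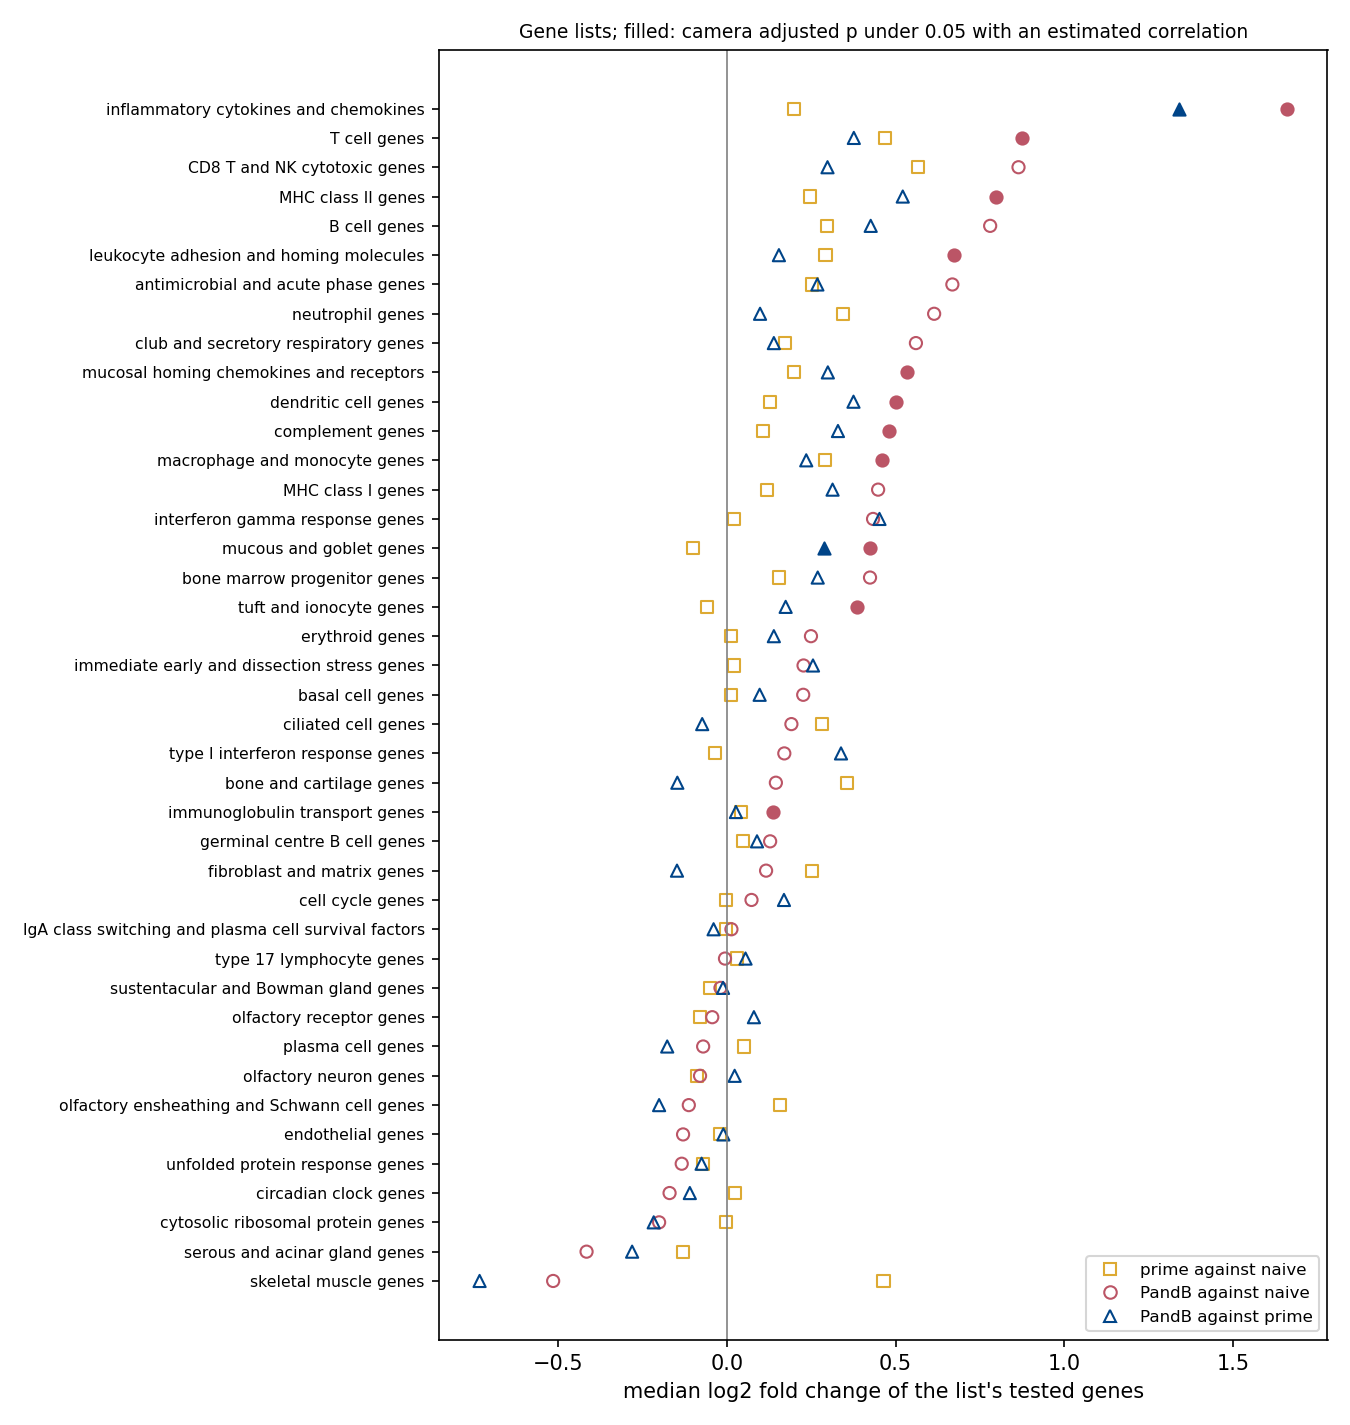
Median log2 fold change of the tested genes of each of 41 fixed lists (horizontal axis) in the comparisons prime against naive (squares), PandB against naive (circles) and PandB against prime (triangles); filled symbols have a camera adjusted p under 0.05 with an estimated correlation. Inflammatory cytokines and chemokines lie farthest right in both PandB comparisons, at 1.66 and 1.34, and no square is filled.

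Priming alone was compared with naive turbinates in the same fit. No gene was called: edgeR, DESeq2 and limma voom each gave 0, and 345 genes had an unadjusted p under 0.05 in edgeR where 620 are expected by chance. The fixed genes stood at 0.07 on the log2 scale for Pigr, 0.20 for Ccl28, 0.50 for Jchain, 0.88 for Mzb1, -0.0038 for Xbp1, 0.25 for Vcam1 and 0.37 for Cd4. Jchain turned to -0.24 without prime replicate 4 and to -0.195 with the olfactory score as a covariate. With the preset correlation 15 lists passed camera, 13 higher and 2 lower, but none passed with an estimated correlation, the lowest adjusted p being 0.417. The 15 included bone and cartilage genes (median 0.36, Acp5 at 0.37), macrophage genes (0.29, C1qc at 0.31) and ciliated cell genes (0.28, Foxj1 at 0.30), with 0 called over all genes or adjusted over the list alone. They also included neutrophil genes (0.34, Csf3r at 1.15) and T cell genes (0.47, Lck at 1.03), with 1 and 2 adjusted over the list alone, and olfactory neuron genes (-0.09, Gfy at -0.26). With an estimated correlation adjusted p was 0.417 for bone, macrophage and T cell genes, 0.583 for neutrophil genes and 0.63 for ciliated and olfactory genes. With the ciliated or the olfactory score as a covariate 3 lists passed in place of 15, and 8, 5 and 8 passed without naive replicate 5, prime replicate 4 and prime replicate 5. Mucous and goblet genes had a median of -0.10 but a mean of 0.297 here.

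Because prime and PandB were both set against the same naive libraries, their fold changes share chance values. Across genes, which are not independent replicates, the 2 comparisons correlated at 0.632 with a covariance of 0.051. In 20 simulations of unchanged groups the correlation averaged 0.54 and the covariance 0.0295, a difference in covariance of 0.0215. Genes were simulated as independent here too, so the simulated libraries hold no differences in tissue makeup. The difference therefore cannot separate a shared response from tissue makeup that libraries of both groups share. With the naive libraries split so that each comparison had its own, the correlation averaged 0.232 over the 10 splits (0.0711 to 0.327) and the covariance 0.0282 (0.0101 to 0.0404). The correlation was 0.315 without prime replicate 4. Signs were the same for 66.8% of genes, against 68.2% in the simulations and 50.6% with split naive libraries. No gene was called after priming, so the calls shared and the number expected of independent lists were both 0.

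In the added contrast of PandB against naive and prime together, 145 genes were called, 107 higher and 38 lower, but without naive replicate 1 the split was 118 higher and 100 lower of 218. The authors' deposited table marked 53 genes as passing, 42 higher and 11 lower, of which 47 were tested here and 26 called. The passing genes had an absolute log2 fold change of at least 1.03 in the authors' deposited table, where 268 genes had an adjusted p under 0.05, while no fold limit was set here. Of the 145 genes called here, 140 had an adjusted p under 0.05 in the authors' deposited table. The genes named for this contrast were chosen after their values were seen. Cxcl5 (1.71), Lcn2 (2.81), Pigr (1.04), Ccl28 (1.37), Csf3 (1.99) and Itgax (1.06) were called here. Cxcl5, Lcn2, Pigr and Ccl28 were past the threshold in all 31 alternatives run, Csf3 in 18 of 23 and Itgax in 10 of 30. Jchain, Mzb1, Krt1, Gh and Obp2b passed in the authors' deposited table, with adjusted p = 0.0396, 0.0391, 0.00621, 4.51e-05 and 0.00826. They were not called here, with edgeR adjusted p = 0.144, 0.0682, 0.125, 0.0886 and 0.13. Mzb1 was past the threshold in 9 of 30 alternatives, Obp2b in 2 of 31, and Jchain, Krt1 and Gh in 1 each. Krt1 was at 85.1 and 73.7 CPM in PandB replicates 6 and 10 and at most 5.98 CPM in the other libraries. Scaling by library totals alone gave 360 higher and 15 lower genes, a share of higher calls of 96% in place of 73.8%. The count was 94 without naive replicate 5, 89 and 80 without prime replicates 1 and 3, and 62 and 76 without PandB replicates 1 and 10.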

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

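The tests of the 3 patterns weighed here used gene lists chosen after the data were seen, and those of the cornified genes and of the time of day were written after the values had been looked at; the covariate tests of Dbp and of the leukocyte genes were written before their results were seen.

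Of 234 values of named genes and library totals tested per group, 9 had a library apart from the rest of its group, where about 12 are expected by chance. The gap between that library and its nearest neighbour was taken as a share of the group's range. Both were measured on a log2 scale with a small constant added to CPM, while the values in brackets are plain CPM. The share was 0.879 for Lsm14b in naive replicate 3 (56.2 CPM against 51.7 to 52.2), 0.764 for Chil1 in naive replicate 4 (65.8 against 21.1 to 27.7), 0.864 for Mpo in naive replicate 4 (1.53 against 8.56 to 10.8) and 0.926 for Laptm5 in naive replicate 3 (25.6 against 35.8 to 36.8). In prime it was 0.745 for C1qb in replicate 5 (75.8 against 84.4 to 87.6), 0.884 for Ccl22 in replicate 4 (2.53 against 3.71 to 3.89), 0.754 for Serpina3n in replicate 2 (238 against 165 to 180) and 0.749 for Crct1 in replicate 4 (10.4 against 0 to 0.838). In PandB it was 0.593 for Ccl20 in replicate 3 (6.8 against 14.6 to 24).

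Genes of cornified squamous epithelium were high in single libraries. Of a list of 46 such genes 13 were tested, and their median stood 3.73 above the mean of naive and prime on the log2 scale in PandB replicate 6 and 4.45 in PandB replicate 10. It was 2.28 in prime replicate 4 and 1.88 in PandB replicate 9, so the pattern is not limited to 2 libraries or to the boosted group. Squamous epithelium taken with some dissections may account for it; Sprr1a, an abundant gene of the list, was at 205 and 544 CPM in PandB replicates 6 and 10, 86.5 CPM in prime replicate 4 and 6.06 to 18.7 CPM in naive. A rise in every boosted library was not seen, since PandB replicates 2 and 3 stood at -0.347 and 0.164, within the range of the naive and prime libraries; the mean of the 5 PandB libraries other than 6 and 10, 0.718 (SE 0.385), leaves open a rise in some of them.

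Dbp was lower in all 7 PandB libraries (74.1 to 121 CPM) than in the 10 others (132 to 193 CPM). Clock genes that peak opposite Dbp minus those that peak with it, Dbp left out (3 and 7 genes), differed in the same direction by 0.633 (SE 0.096), and the 7 PandB libraries were all above the others (exact two-sided permutation p = 5.14e-05, the smallest that the 19448 splits can give). Dilution by leukocyte RNA is argued against, since the PandB coefficient of log2 Dbp was -0.73 (SE 0.111) without and -0.876 (SE 0.174) with a pan-leukocyte score as a covariate. Another time of day of collection is a candidate explanation. The labels give no hour, so it cannot be separated from an effect of the boost on the clock, which was not tested. The limit is not confined to Dbp. A different hour or session of collection for the PandB libraries would be confounded with the boost for every gene and list in the PandB comparisons.

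Leukocyte genes were higher in PandB, with Ptprc at 1.36, Laptm5 at 0.98 and Cd52 at 1.31 on the log2 scale against naive, all called. Prime replicates 4 and 5 reached the PandB range for Ptprc (18.4 and 15 CPM against 14.9 to 28.2) and Cd52 (96.4 and 95.3 against 83.7 to 162). For Laptm5 only prime replicate 5 did (50.6 and 56.3 against 53 to 94). The PandB coefficient of a pan-leukocyte score of 12 genes, taken against naive and prime together, was 0.636 (SE 0.135). This coefficient stayed at 0.572 (SE 0.118) with a bone marrow progenitor score as a covariate, which argues against marrow as the whole source. With an erythroid score it stayed at 0.585 (SE 0.127). The erythroid gene Alas2 and the marrow gene Mpo were both highest in PandB replicate 3 (95.3 and 40.4 CPM). Both were lowest in prime replicate 2 (15.2 and 0.973 CPM). The erythroid score may thus follow marrow, and blood with more leukocytes per red cell would not move it. Blood as a source was therefore not decided. With a B cell score the PandB coefficient was 0.393 (SE 0.0769), so lymphoid tissue in the dissections may hold part of the rise. That tissue cannot be told apart from the rise, because a rise of B cell genes with the boost was neither shown nor excluded. The B cell score of PandB differed from naive and prime by 0.481 (exact two-sided permutation p = 0.0545). Cd79b averaged 7.1 CPM in naive, 14.2 CPM in prime and 14.3 CPM in PandB, where replicate 10 held 36.6 CPM. Recruitment of leukocytes after the boost stays open as the untested biological explanation.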

How the results depend on the processing

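Alternatives described as added in the methods, and every alternative of the added contrast and of the correlation, were chosen after the data were seen; the rest were planned. The cause of a change was not tested unless it is stated.

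With library totals alone the gene counts were 214 (PandB against naive), 52 (against prime) and 375 (against both), since that scaling moved the median gene; DESeq2 gave 189, 54 and 262. Without PandB replicates 6 and 10 they were 41 against naive and 65 against both; without the 2 shallowest libraries, 47 against naive and 4 against prime. The olfactory score as a covariate gave 65 against prime and 255 against both, the ciliated score 87 and 289, and the ribosomal score 8 and 59. Against naive the ribosomal score gave 70, 67 higher and 3 lower. Of the genes called with the ribosomal score, 43 against naive, 5 against prime and 42 against both were also called in the main fit. The replicate numbers did not pair the samples: same-numbered libraries correlated at -0.345 to 0.386, over 0.1 in 2 of 5, 1 of 4 and 1 of 4 pairs. The best match was the library of the same number in 1 of 5, 0 of 4 and 0 of 4 pairs. With the number as a block the counts were 58, 13 and 70, of which 36, 10 and 51 genes were also called in the main fit.

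Lists for prime against naive numbered 3 with the olfactory or the ciliated score, and 0 with an estimated correlation or fry. For PandB against naive 11 passed with an estimated correlation. Against prime 2 did, while 4 passed with fry and 17 with the stricter filter, which tests fewer genes. That filter left too few members to test some lists, the inflammatory, T cell and dendritic cell lists among them. The correlation of the comparisons that share the naive libraries was 0.517 with the olfactory score, 0.714 with the ribosomal score, 0.515 with the ciliated score, 0.518 without PandB replicates 6 and 10 and 0.512 with voom.

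Leaving out each library gave 0 genes throughout for prime against naive, 35 to 115 for PandB against naive (59 without naive replicate 2 or 3, 60, 57 and 49 without PandB replicates 2, 6 and 10), 7 to 35 against prime and 62 to 218 against both. Without naive replicate 1 the calls split into 46 higher and 58 lower against naive and into 118 higher and 100 lower against both. Lists ran from 5 to 21 for prime against naive (5 without prime replicate 4, 8 without naive or prime replicate 5), 23 to 30 and 19 to 25, and the correlation from 0.315 without prime replicate 4 to 0.756. Of genes called against naive, C3 and Ccl22 lost the call in 13 of 17 such fits and Icam1 in 12, and against prime Rtl8a and Cd72 in 12. In the added contrast Itgax lost it in 12 of 17.

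The direction of a list is that of its test. Xbp1 went to 0.22 and 0.15 in the PandB comparisons with the ribosomal score. For prime against naive it was 0.059 with totals alone, 0.0014 with the stricter filter, 0.0313 with the block, 0.0667 with the ribosomal score, 0.018 without the shallowest libraries, 0.0013 with only the groups compared and 0.0536 with voom, and -0.12 to 0.075 leaving out each library. Vcam1 against naive was -0.20 (olfactory), -0.16 (ciliated), -0.0346 (shallowest out) and -0.0513 (voom), and -0.14 to 0.18 leaving out each library; for prime it was -0.020 (olfactory). Jchain for prime was -0.195 (olfactory) and -0.198 (ciliated), and -0.24 to 1.31 leaving out each library, and Pigr for prime -0.053 to 0.16. With the ribosomal score the median of gland genes turned from -0.416 to 0.117 against naive (adjusted p = 0.257) and from -0.281 to 0.242 against prime (adjusted p = 0.00597), the second past the threshold in the other direction. Unfolded protein response genes turned to 0.0367 and 0.0956, and ribosomal genes against naive to 0.00769 with their own score. Muscle genes against prime turned from -0.733 to 0.192, and to 0.252 without the shallowest libraries. Olfactory neuron genes against naive kept a negative median of -0.0055 with their own score, but the direction of the test turned.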

Other observations

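The tests of the component, of the split naive libraries and of the added contrast in this part were chosen after the data were seen; the counts of splits for the planned comparisons were not.

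Some transcripts varied widely between libraries of the same group; the genes named here were chosen after their values were seen. Gh, which encodes growth hormone, ranged from 4.08 to 146 CPM in naive, from 3.09 to 234 CPM in prime and from 0.293 to 5 CPM in PandB. Obp2a, an odorant-binding protein of the nasal glands, was at 45900 ± 22400 CPM (SD, n = 5) in naive, 40800 ± 11900 CPM (SD, n = 5) in prime and 22000 ± 6500 CPM (SD, n = 7) in PandB, with an edgeR log2 fold change of -1.06 against naive (adjusted p = 0.209).

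The first principal component, which held 20.9% of the variance, crossed the groups and followed the tissue makeup of the libraries. Over the 17 libraries it correlated with the ciliated cell score (Pearson r = 0.932, Spearman rho = 0.922, permutation p = 1e-05 for both, the smallest that 100000 permutations give, adjusted p = 5e-05), with the olfactory neuron score (r = -0.865, permutation p = 2e-05, rho = -0.809, permutation p = 0.00015) and with the bone and cartilage score (r = 0.874, permutation p = 3e-05, rho = 0.789, permutation p = 0.00024); 5 scores were tested, and adjusted p was at most 4e-04 for these 3. Without the 2 libraries farthest from the median score r was 0.911, -0.767 and 0.819. The ribosomal protein score gave r = -0.0387 (permutation p = 0.88, rho = -0.157, permutation p = 0.55) and the marrow progenitor score r = 0.32 (permutation p = 0.21, rho = 0.377, permutation p = 0.14). The second component, with 12.3% of the variance, ran from 5.83 to 18.2 in PandB. It ran from -28.5 to 8.04 in naive and from -22.2 to -0.849 in prime, and was not tested against the scores.

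Other splits of the libraries bear on whether chance could give the counts. Against naive, 1 of 100 splits, the real one, gave 93 genes (highest other 6), and 3 of 100 gave 27 or more lists (highest other 29). Both shares are under 0.05, from 100 of 792 possible splits and without adjustment over the comparisons. List counts here use the preset correlation. Such splits bear on random grouping only, since a tissue makeup or collection time that went with the groups would also set the real split apart. Against prime, 4 of 100 splits gave 23 or more genes and 1 of 100 gave 26 lists (highest other 25). The highest other gene count there was 342, from a split that put prime replicates 1, 2 and 3 with PandB replicates 2, 3, 4 and 6. Their ciliated cell scores were 5.06 to 5.55, against 5.79 to 6.54 in the other prime and PandB libraries. That split thus followed the tissue makeup seen in the first principal component, which the labels do not name. With the ciliated cell score as a covariate the real groups gave 87 genes. For prime against naive, 19 of 100 splits gave 15 or more lists (highest other 23), so chance is not excluded for the lists. The real gene count there was 0, which all 100 splits reach by construction (highest other 84), so that count says nothing about chance. In the added contrast 1 of 100 splits gave 145 genes (highest other 46).

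A hypothesis that priming holds part of the change seen after the boost was tested with 100 genes of lowest p in PandB against 3 naive libraries, measured against the other 2 in all 10 splits. The median change of prime in the direction of PandB ran from -0.29 to 0.171 on the log2 scale and was over 0 in 6 of 10 splits. That of PandB against the same libraries ran from 0.0572 to 0.655. The same PandB libraries chose the genes, which raises this second range, so it is no fair yardstick for prime. The data leave the hypothesis open.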
